A study of Mus musculus with 6 samples.

How the data were processed

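Gene expression was measured in hearts of 6 mice aged 12 months, 3 wild-type and 3 with a knockout of Cenpf, on Affymetrix mouse gene arrays, with 1 array per heart. Total RNA was isolated with Trizol, cleaned on RNeasy columns and labelled with biotin, per the labels' protocols. The labels call the 3 hearts of each group biological replicates. The strain, the sex of the mice and the part of Cenpf that was deleted are not given in the sources used here.

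The deposited values are on a log2 scale. The tools named are RMA, which corrects background, normalizes arrays to each other and summarises probes, and Partek 6.6, per the submitters' processing notes. Their settings, the probe annotation the authors used and a genome build are not given in the sources used here. The deposited log2 values of the 6 arrays had medians between 6.92 and 6.97 over all 35556 probes. These lay within 0.1 of each other, so no further normalization was applied for the results reported. No pseudocount was needed and no probe was left out for low signal.

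Probes were named from the array's annotation table, and symbols were looked up by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6. Exactly 1 gene symbol was given for 21789 probes, several for 1621, and 12146 probes were unnamed here. The gene table held 21698 of the 21789 identifiers, and 0 symbols needed updating. The 21789 probes stand for 19939 genes, of which 998 had more than 1 probe. The gene table served only for names and for which genes neighbour each other, so no coordinates are given.

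A background level was set at the 95th percentile of the mean log2 values of 1212 olfactory and vomeronasal receptor probes, genes taken as silent in heart. It was 6.35 on the log2 scale, and 71.2% of the 21789 probes had a mean above it. An array's depth is not defined as for reads, and the number of arrays limits the precision.

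Knockout and wild-type hearts were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values, two-sided, with Benjamini-Hochberg adjustment over the 21789 probes. Fold changes are knockout minus wild-type. A probe was called at an adjusted p under 0.05. A second, descriptive count took probes at an unadjusted p under 0.01 and a change of at least 1.5-fold. For Cenpf an exact two-sided permutation test of the 6 values was added, whose smallest possible p is 0.1.

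Gene lists, 48 in number, were fixed before the data were examined. They covered heart muscle, metabolism, cell cycle, stress responses and markers of the cell types a heart sample can hold. Each gene entered with its probe of highest mean. Lists were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 48 lists, and again with an estimated correlation and with fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes.

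The genes named were chosen by a rule fixed before the data were examined. It took Cenpf, then Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2 and Nnt whatever their values. It took the 10 largest rises and 10 largest falls among called probes whose groups did not overlap. Each side was filled up with the largest non-overlapping changes at an unadjusted p under 0.01, which are given as not having passed. Predicted genes, olfactory and vomeronasal receptors, small RNA genes and genes below the background level in both groups were passed over there. It also took the 4 members with the smallest p of each shifted list, 2 of any other list described, and Xist with the highest Y-linked gene as a check of sex. Which of the unshifted lists to describe was decided after the results were seen.

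The gene test was run on simulated data built from the means and residual spread of the 21789 probes, with 200 changed genes in each of 20 simulations of 3 against 3 arrays. At an adjusted p under 0.05 it recovered 77.6% of genes changed 2-fold and 97.6% of genes changed 4-fold, with a mean of 8.2 false calls. The simulated genes varied independently and with the same spread in every array, so these shares need not hold for the real arrays. The list test found 100% of lists shifted by 0.3 on the log2 scale when genes varied independently, and called a mean of 0.6 lists that had not been shifted as lists of their own. In the real arrays genes of a list varied together, with an estimated correlation of 0.64 for cytoplasmic ribosomal proteins. The rates of the list test need not hold there.

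The alternatives tried were 3 other normalizations, 2 filters on dim probes and 1 more chosen after seeing the data, all probes of the table as the tested family, the mean of a gene's probes, a trend and robust variance model, array weights and a plain linear model. The replicate number as a block and each array left out in turn were also run, as were other thresholds and the other list tests. Figures were drawn with matplotlib 3.10.9.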

Results

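Transcript levels were compared between 12-month hearts of 3 wild-type mice and 3 mice with a knockout of Cenpf, 1 array per heart. Cenpf encodes centromere protein F, a large protein of the kinetochore that binds microtubules. The question the study names is how the hearts of the knockout mice differ from wild-type hearts. The replicates are labelled as biological, so the spread between them includes differences between mice. With 3 hearts a group, the number of arrays limits the precision.

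Cenpf, measured by 1 probe (10360985), read 8.75, 8.54 and 8.04 in the wild-type hearts and 6.35, 6.10 and 6.68 in the knockout hearts, on the log2 scale. The group means were 8.44 ± 0.36 (SD, n = 3) and 6.37 ± 0.29 (SD, n = 3), and the background level was 6.35. Cenpf fell by 2.07 in the knockout hearts, with a standard error of 0.21 (limma, adjusted p = 0.0286). Of the 3 knockout values 2 lay below the background level, so how much transcript remained was not resolved. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 allows. The part of Cenpf that was deleted is not given, so this probe checks the labels only as far as it lies in that part. Every knockout value lay below every wild-type value. The adjusted p was 0.0905 without wild-type replicate 1 and 0.198 without wild-type replicate 2. It was 0.123, 0.114 and 0.0689 without knockout replicates 1, 2 and 3, within a range of 0.00508 to 0.476 over all alternatives.

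In the knockout hearts 3 probes were higher and 3 lower at an adjusted p under 0.05, out of 21789. Mmp3, which encodes a secreted protease of the extracellular matrix, rose from 5.99 ± 0.17 to 8.02 ± 0.25 (SD, n = 3), a fitted difference of 2.03 with a standard error of 0.15 (adjusted p = 0.00672). Its wild-type mean lay below the background level of 6.35, so the rise is given as at least 1.67 above that level. Pagr1a, which encodes a partner of the PAXIP1 protein, rose by 1.53 with a standard error of 0.13, from 8.03 ± 0.23 to 9.56 ± 0.05 (SD, n = 3, adjusted p = 0.0124). Zfp943, which encodes a zinc finger protein, fell by 1.14 with a standard error of 0.11, from 9.08 ± 0.16 to 7.94 ± 0.03 (SD, n = 3, adjusted p = 0.0243). Cenpf was the second named fall. The other 2 called probes belong to an olfactory receptor gene, Olfr872, below the background level in both groups, and to a small nucleolar RNA gene, Snord53.

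Of these 6 calls only that of Olfr872 was kept without each of the arrays in turn, with adjusted p from 0.00211 to 0.0169. Snord53 did not pass without any 1 array other than wild-type replicate 3, with adjusted p from 0.111 to 0.291. Pagr1a and Zfp943 did not pass without any 1 array other than wild-type replicate 3, with adjusted p from 0.0708 to 0.0863 and from 0.0863 to 0.142. Mmp3 did not pass without wild-type replicate 1 (adjusted p = 0.0531) or wild-type replicate 2 (adjusted p = 0.0736). Over all alternatives the adjusted p reached 0.414 for each of these 3 genes. Without wild-type replicate 3 there were 293, standing for 273 genes, of which 169 probes were higher and 124 lower, and all 6 were among them. Without wild-type replicate 1 or wild-type replicate 2 there was 1 call each, and without knockout replicate 2 or 3 there were 3, with 2 higher, and 2, both higher. Without knockout replicate 1 there were 6, all higher, of which 2 were among the original calls. At an unadjusted p under 0.05 there were 2157 probes, where 1089 are expected by chance on average. Since probes vary together across arrays, a single comparison can lie far from that average by chance.

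At an unadjusted p under 0.01 and a change of at least 1.5-fold, 186 probes differed, 91 higher and 95 lower in the knockout hearts. Of these 153 lay above the background level in at least 1 group and 45 changed 2-fold or more. Without wild-type replicate 3 the count was 565, with 302 higher and 263 lower, and without wild-type replicate 2 it was 121, with 58 and 63. Without wild-type replicate 1 the even split was lost, with 52 higher and 150 lower, as it was over all probes of the table, with 148 and 289. Over all probes, 14.8% had groups that did not overlap, where chance gives 10% on average for 3 against 3. Probes vary together across arrays, so the share of a single division can lie away from 10% by chance. It was not computed for other divisions of the arrays.

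**Figure D1:**
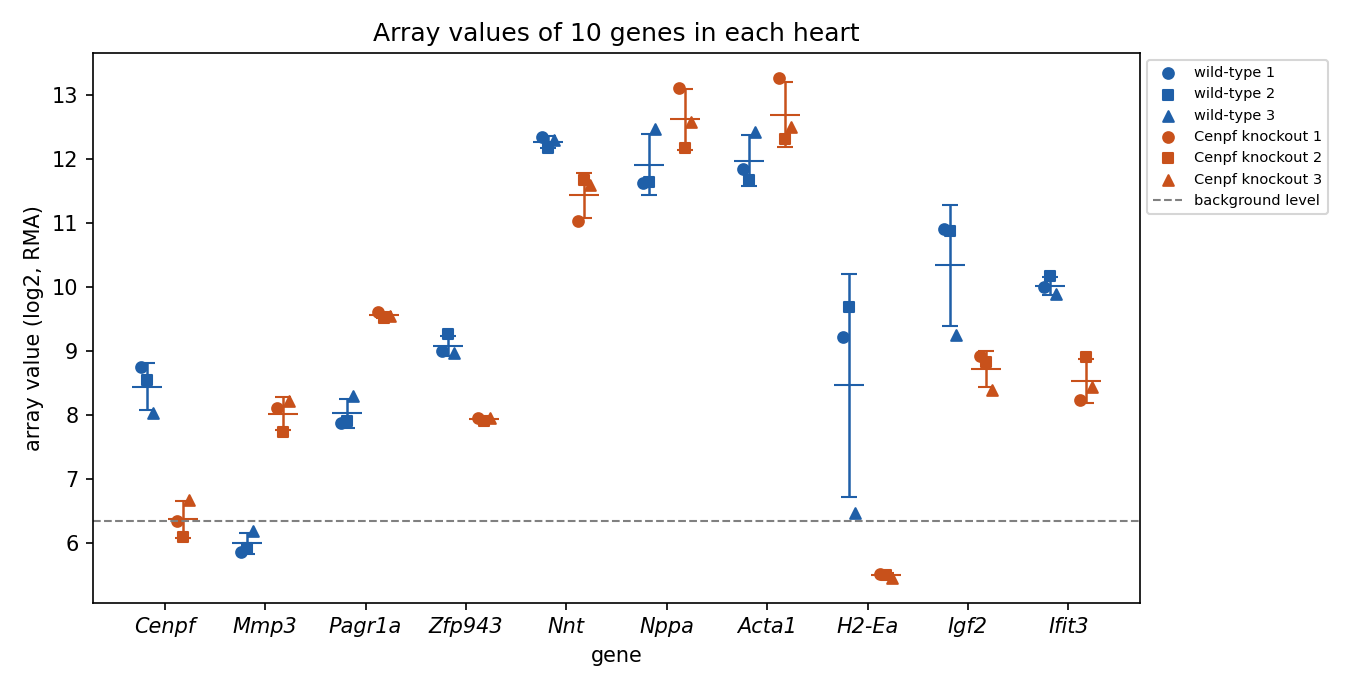
Array values on the log2 scale (vertical axis) of 10 genes (horizontal axis) in each of the 3 wild-type hearts (blue) and 3 Cenpf knockout hearts (orange); bars are the group mean ± SD and the dashed line is the background level of 6.35. Cenpf read 8.04 to 8.75 in wild-type and 6.10 to 6.68 in knockout hearts, and H2-Ea read 9.23, 9.69 and 6.47 in wild-type replicates 1, 2 and 3.

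Outside these calls, the largest non-overlapping differences did not pass the adjusted threshold and are given as values. On the higher side were Bcap29 with 2.04, Cd209f with 2.01, Heatr5b with 1.98, Nr4a1 with 1.74 and Gabra3 with 1.70. Lbp, the lipopolysaccharide-binding protein, differed by 1.63, the relaxin receptor Rxfp1 by 1.54 and Cd209d by 1.54. Their adjusted p lay between 0.110 for Gabra3 and 0.379 for Cd209d. Heatr5b and Cd209d lay below the background level in wild-type hearts, so their differences are at least 1.16 and 1.11, the second at least 0.67 without knockout replicate 1. Cd209f, Gabra3 and Rxfp1 lay little above that level of 6.35 in wild-type hearts, at 6.46, 6.39 and 6.58. The sizes of their differences are therefore less certain. The 2 Heatr5b probes disagreed, since the other one differed by 0.22. On the lower side were the class II histocompatibility chain H2-Ea with -2.97, the carbonic anhydrase Car3 with -2.29, BC023105 with -1.83, Gpr75 with -1.75 and the growth factor Igf2 with -1.63. Ifit3, an interferon-induced gene, differed by -1.50 (adjusted p = 0.0502), and the water channel Aqp4 by -1.45. H2-Ea and BC023105 lay below the background level in knockout hearts, where their means were lower by at least 2.11 and 1.31. Without knockout replicate 1 the difference of BC023105 was -1.20. The largest fitted difference of all, -6.74 (adjusted p = 0.0502), at least 5.89 in size since the knockout mean lay below the background level, came from a probe annotated as Kcnma1. None of its 20 neighbours in probe order lies on the chromosome of Kcnma1, and the other Kcnma1 probe, below the background level in both groups, differed by -0.25, so the name of this probe is uncertain. Neighbours in probe order were looked up only for the named rises and falls, not for the other genes named here. Of the 20 named rises and falls, 4 passed with all arrays and 15 without wild-type replicate 3. These genes were picked from the same arrays, and wild-type replicate 3 lay nearest the knockout hearts. The choice thus favours this rise, which gives no independent support. Ifit3 passed in 9 of its 18 alternatives and the Kcnma1 probe in 7 of 18, with adjusted p from 0.0145 to 0.500 and from 0.000142 to 0.533. Both passed with array medians subtracted, with either planned filter on dim probes, the mean of a gene's probes, which put Kcnma1 at -3.49, array weights, the replicate block and without wild-type replicate 3. Ifit3 also did with the trend model and without knockout replicate 2. Nr4a1 and Gabra3 passed in 4 alternatives each, Heatr5b in 2 and Gpr75 in 1.

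The markers of heart failure and contraction fixed beforehand gave no call. Nppa and Nppb, which encode the natriuretic peptides, differed by 0.71 (adjusted p = 0.485) and 0.52 (adjusted p = 0.589). The skeletal actin gene Acta1 differed by 0.72 (adjusted p = 0.472). Of the myosin heavy chains, Myh6 differed by 0.05 (adjusted p = 0.902) and Myh7 by -0.51 (adjusted p = 0.556). Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by 0.06 (adjusted p = 0.867). Leaving out 1 array moved these values, Nppa from 0.46 without knockout replicate 1 to 0.99 without wild-type replicate 3, and Nppb from 0.27 to 0.83 and Acta1 from 0.43 to 0.94 without the same arrays. Myh7 ranged from -0.85 without knockout replicate 1 to -0.28 without knockout replicate 3, Myh6 from -0.023 without knockout replicate 2 to 0.14 without knockout replicate 1, and Atp2a2 from 0.016 without wild-type replicate 2 to 0.12 without knockout replicate 1. Nnt, the mitochondrial transhydrogenase, which carries a deletion in some mouse strains, read 12.28 ± 0.09 in wild-type and 11.44 ± 0.35 in knockout hearts (SD, n = 3, adjusted p = 0.263), and its groups did not overlap. Xist read 5.87 and 5.96 in the 2 groups, below the background level, while the Y-linked Eif2s3y read 10.06 and 9.83. By this check of sex the hearts of both groups read as male, which the labels do not give.

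By the list test, 14 of 48 gene lists were shifted, 8 upward and 6 downward, at an adjusted p under 0.05 with the preset correlation. With an estimated correlation 0 lists passed the adjusted threshold and 3 passed unadjusted, namely the immediate early, erythrocyte and lymphatic lists. By fry 0 passed adjusted and 5 unadjusted. Among the shifted lists, 7 had array means that did not overlap between the groups. Other ways of dividing the same 6 arrays gave up to 18 shifted lists. Adjusted over all probes tested, 0 members of any of the 48 lists passed. Without wild-type replicate 3 50 of their 1140 genes did, 37 higher, and at most 1 without any other array.

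Immediate early genes, which are transcribed quickly after a stimulus, were shifted upward, with 21 of 24 members higher and a mean difference of 0.43 (adjusted p = 5.64e-11, and adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 9 members passed, all higher. Nr4a1 differed by 1.74, the transcription factor Egr1 by 0.77, the phosphatase gene Dusp1 by 0.63 and Ccn1 by 0.55. The list means of the 3 knockout hearts, 0.11 to 0.32 above the mean of all arrays, lay above those of the wild-type hearts, -0.28 to -0.12. Heat shock and oxidative stress genes were shifted upward by a mean of 0.17 (adjusted p = 0.000305, and adjusted p = 0.726 with an estimated correlation). Of their 26 members 19 were higher, and 1, Hspa1a with 0.77, passed adjusted over the list alone, or 12 without wild-type replicate 3. Txnip, Cat and Dnajb1 differed by 0.42, 0.43 and 0.35.

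Genes of fatty acid uptake and oxidation were shifted upward, with 37 of 42 members higher and a mean of 0.23 (adjusted p = 2.21e-07, and adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone, 2 passed, the uncoupling protein gene Ucp3 with 1.44 and the pyruvate dehydrogenase kinase gene Pdk4 with 1.46. That count was 9 without wild-type replicate 3 and 0 without any other array. Slc25a20 and Cpt1a differed by 0.46 and 0.34. Wild-type replicate 3, at 0.04, lay above knockout replicate 1, at 0.0071, in this list's array means. Genes of respiratory complex I were shifted downward by a mean of -0.07, with 30 of 43 members lower (adjusted p = 0.0266, and adjusted p = 0.741 with an estimated correlation). Complexes III, IV and V were shifted downward by -0.07, with 28 of 37 members lower (adjusted p = 0.0180, and adjusted p = 0.845 with an estimated correlation). In both, 0 members passed adjusted over the list alone. Among their lowest p were Ndufaf4 with -0.38, Ndufaf2 with -0.32, Ndufa5 with -0.26 and Ndufa12 with 0.23. In the other list these were Cox8a with -0.29, Uqcrh with -0.25, Atp5j2 and Cox6b1, both with -0.21. Leaving out wild-type replicate 1 or 2 or knockout replicate 1 ended both calls, with adjusted p from 0.0546 to 0.127, as did knockout replicate 2 for complex I (adjusted p = 0.122) and cyclic loess normalization for the other list (mean -0.042, adjusted p = 0.120). Over all alternatives the adjusted p ranged from 0.00354 to 0.741 for complex I and from 0.000783 to 0.845 for the other list.

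Cytoplasmic and mitochondrial ribosomal protein genes were shifted downward. Of 61 cytoplasmic members 53 were lower, with a mean of -0.12 (adjusted p = 4.15e-05, and adjusted p = 0.859 with an estimated correlation). Of 74 mitochondrial members 59 were lower, with a mean of -0.11 (adjusted p = 0.000986, and adjusted p = 0.859 with an estimated correlation). In both lists 0 members passed adjusted over the list alone, though 7 mitochondrial ones did without wild-type replicate 3. In the cytoplasmic list knockout replicate 1, at 0.095, lay above wild-type replicates 1 and 3, at 0.048 and -0.013. Its mean was -0.20 without knockout replicate 1, -0.079 without wild-type replicate 2 and -0.065 without knockout replicate 2. In the mitochondrial list wild-type replicate 3, at -0.072, lay below knockout replicates 1 and 3, at -0.051 and -0.0092, and without it the mean was -0.17. Rps28 differed by -0.41, Rps29 by -0.33, Rpl10a by -0.28 and Rpl23 by -0.26, while Mrpl32 differed by -0.43, Mrps11 by -0.41, Mrps31 by -0.32 and Mrpl28 by 0.30. The names of these probes were not checked by their neighbours in probe order.

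Natriuretic and fetal cardiac stress genes were shifted upward by a mean of 0.37, with 17 of 21 members higher (adjusted p = 4.57e-05, and adjusted p = 0.726 with an estimated correlation). Adjusted over the list alone, 1 member passed, Uchl1, at 6.98 in wild-type and 7.98 in knockout hearts. That count was 12 without wild-type replicate 3, 2 without knockout replicate 3 and 0 without wild-type replicate 1 or knockout replicate 2. Mybpc2 differed by 1.04, Rcan1 by 0.55 and Myl7 by 0.53, or 0.33 without wild-type replicate 2. Knockout replicate 1 stood highest at 0.47, and the call was lost without it (mean 0.22, adjusted p = 0.0648, range over the alternatives 5.28e-07 to 0.726). Wild-type replicate 3, at 0.098, lay above the other knockout hearts, at 0.040 and 0.037. Knockout replicate 1 also stood highest for fibroblast markers, at 0.43 against -0.26 and -0.13 in knockout replicates 2 and 3, for macrophage and monocyte markers, at 0.37 against -0.30 and -0.20, and for matrix genes, at 0.35 against -0.14 and -0.11. Its ventricular cardiomyocyte markers lay lowest, at -0.12 against 0.10 and 0.057. Genes of muscle atrophy, ubiquitin ligases and autophagy were shifted upward by 0.13, with 18 of 26 higher (adjusted p = 0.0104, and adjusted p = 0.726 with an estimated correlation). The ubiquitin ligase genes Fbxo32 and Trim63 differed by 0.60 and 0.43, Gabarapl1 by 0.56 and Bag3 by 0.39, and 0 passed adjusted over the list alone, or 6 without wild-type replicate 3. Without wild-type replicate 1 this call was lost (adjusted p = 0.0819, range over the alternatives 0.000412 to 0.726), and without wild-type replicate 3 the mean was 0.20.

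Kinetochore and mitosis genes, a list that left out Cenpf itself, were shifted upward by a mean of 0.12, with 29 of 52 members higher (adjusted p = 0.010, and adjusted p = 0.726 with an estimated correlation). Only 32 of the 52 lay above the background level in at least 1 group. With only the members whose mean over all arrays lay above it, the list did not pass (adjusted p = 0.124). Nor did it pass over probes above the background level (adjusted p = 0.342), above the median of all probes (mean 0.076, adjusted p = 0.935) or, with a filter added after the data were seen, above the median of probes with 1 symbol (mean 0.050, adjusted p = 0.898). Ccna2 differed by 0.76. Anln, the 1 member that passed adjusted over the list alone, and Top2a lay below the background level in wild-type hearts and at 6.39 and 6.52 in knockout hearts, too near that level for a size to be given. Prc1 lay below it in both groups. The count over the list alone was 10 without wild-type replicate 3, 2 without knockout replicate 3 and 0 without any other array. Without wild-type replicate 1 or knockout replicate 1 the call was also lost (adjusted p = 0.120 and adjusted p = 0.0763, range over the alternatives 0.00038 to 0.935).

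Interferon response genes were shifted downward, with 26 of 29 members lower and a mean of -0.24 (adjusted p = 2.80e-06, and adjusted p = 0.726 with an estimated correlation). Ifit3 with -1.50 and Iigp1 with -0.85 passed adjusted over the list alone, while Usp18 and Ifi27 differed by -0.54 and -0.38. Without knockout replicate 1, whose list mean of 0.047 stood above -0.16 and -0.25 in the other knockout hearts, 9 passed over the list alone. Among markers of other cell types, those of erythrocytes were shifted upward by 0.44 in all 6 members (adjusted p = 2.80e-06, and adjusted p = 0.292 with an estimated correlation). Of these 5 passed adjusted over the list alone, among them Alas2 with 0.88, Slc4a1 with 0.54 and Bpgm with 0.45, and also Epb42, which lay below the background level in both groups. Without wild-type replicate 2 or knockout replicate 3 that count was 3. Lymphatic endothelial markers were shifted upward by 0.37 (adjusted p = 0.0174, and adjusted p = 0.691 with an estimated correlation). Mmrn1 with 1.13, Reln with 0.66 and Flt4 with 0.62 passed adjusted over the list alone, and Lyve1 differed by -0.31, ranging from -0.57 without knockout replicate 1 to -0.14 without knockout replicate 2. This call was lost without knockout replicate 1 (adjusted p = 0.101), whose list mean of 0.36 stood above 0.14 and 0.050 in the other knockout hearts, with array weights (adjusted p = 0.0560) and over probes above the median of all probes (adjusted p = 0.0507) or of those with 1 symbol (adjusted p = 0.0602), in a range of 0.00637 to 0.691. Adipocyte markers were shifted downward by a mean of -0.34, with 13 of 16 lower (adjusted p = 0.00675, and adjusted p = 0.726 with an estimated correlation). Car3 with -2.29 passed adjusted over the list alone, where 6 did without wild-type replicate 3 and 0 without wild-type replicate 2 or any knockout array, and Retn, Scd1 and Plin1 differed by -0.85, -0.60 and -0.33. Without wild-type replicate 1 Retn differed by -0.48. The call of the adipocyte list was lost without wild-type replicate 1 (mean -0.21, adjusted p = 0.0668) and over probes above the median of those with 1 symbol (mean -0.41, adjusted p = 0.0742, range over the alternatives 0.000842 to 0.726).

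**Figure D2:**
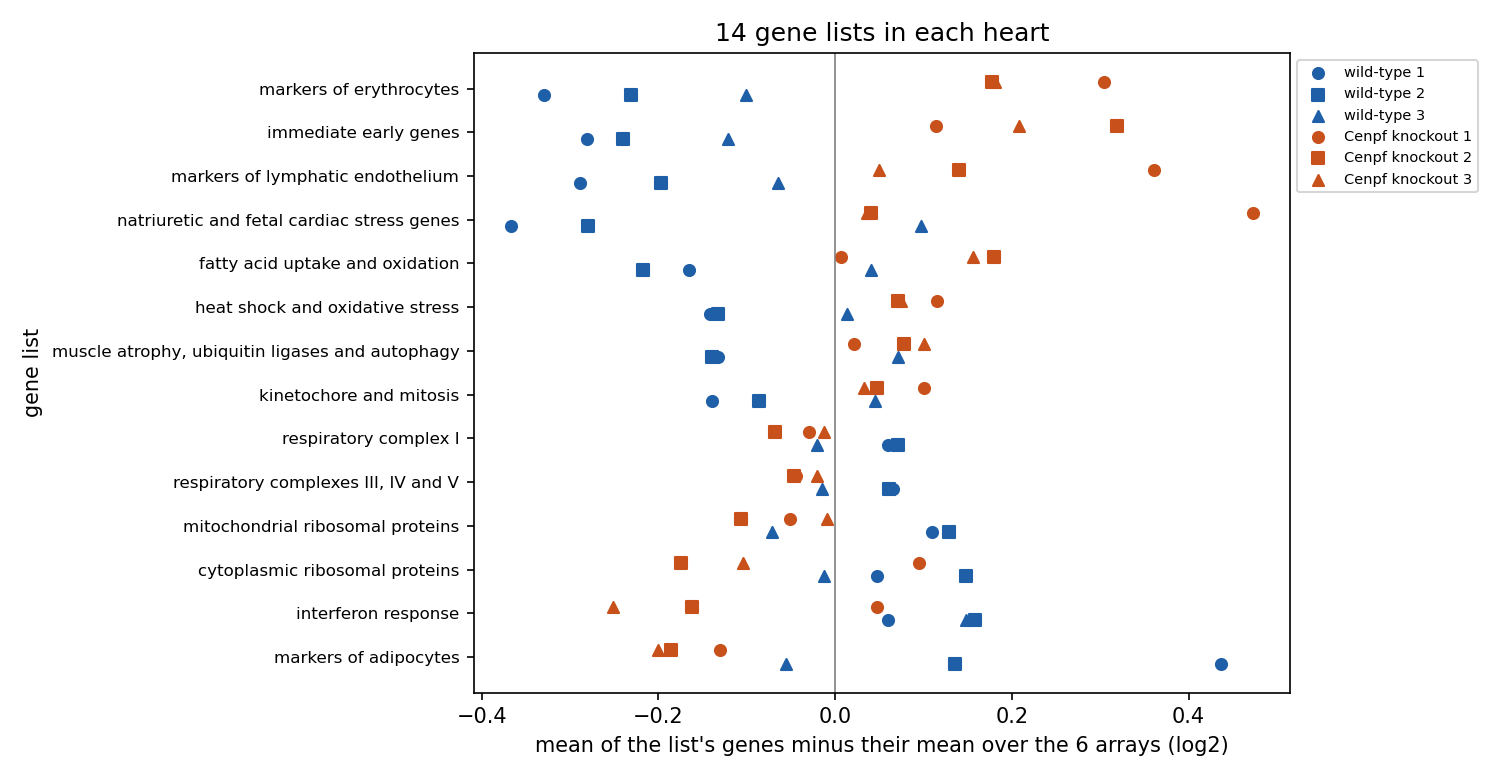
Mean of the genes of each of the 14 shifted lists (vertical axis) in each heart, relative to the mean of all 6 arrays, on the log2 scale (horizontal axis); blue marks are wild-type and orange marks Cenpf knockout hearts. Immediate early genes lay at 0.11 to 0.32 in the knockout hearts and at -0.28 to -0.12 in the wild-type hearts.

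The other 34 lists did not pass, with adjusted p from 0.154 to 0.966. Genes of the cardiac sarcomere and Z-disc had a mean of 0.06 over 29 members (adjusted p = 0.326), with Myom1 at 0.26 and Nebl at -0.29. That mean ranged from 0.023 without wild-type replicate 2 to 0.11 without wild-type replicate 3. Myom1 was at 0.17 without wild-type replicate 2, and Nebl at -0.19 without knockout replicate 1 and at -0.16 in the mean of its probes. Calcium handling genes had a mean of 0.09 (adjusted p = 0.192), with Camk2b at 0.48 and Jph1 at 0.47, and passed without knockout replicate 1 (mean 0.14, adjusted p = 0.0178), while the mean was 0.048 without wild-type replicate 2 or knockout replicate 2. Tubulins and microtubule-associated proteins had a mean of 0.05 over 43 members (adjusted p = 0.233), with Map1a at 0.38 and Mapre3 at 0.31, and of 0.030 and 0.078 without wild-type replicates 1 and 3. Genes of the costamere, focal adhesion and intercalated disc had a mean of 0.03 (adjusted p = 0.272), with Sntb1 at -1.02 and Itgb5 at 0.30, and passed without knockout replicate 1 (mean 0.10, adjusted p = 0.00719). Its mean turned to -0.016 without knockout replicate 2 and was 0.013 and 0.011 without wild-type replicate 2 and knockout replicate 3.

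Extracellular matrix and fibrosis genes had a mean of 0.06 (adjusted p = 0.183), with Acta2 at -1.28 and Thbs1 at 0.62, or 0.34 without wild-type replicate 1. That list passed without wild-type replicate 2 (adjusted p = 0.0138), knockout replicate 2 (adjusted p = 0.00499) or knockout replicate 3 (adjusted p = 0.00597), and its mean turned to -0.097 without knockout replicate 1 and -0.0067 without wild-type replicate 3. Potassium and sodium channels and connexins had a mean of -0.0060 (adjusted p = 0.966), with Scn4b at 1.12 and Kcnj5 at -0.51. Without knockout replicate 1 the list passed upward (mean 0.14, adjusted p = 0.0144) and Kcnj5 was at -0.32, while without knockout replicate 3 the mean was -0.091. DNA replication genes had a mean of 0.02 (adjusted p = 0.705), with Rrm1 at -0.35 and E2f8, below the background level in wild-type hearts, higher by at least 0.30. That mean ranged from -0.016 without wild-type replicate 3 to 0.043 without wild-type replicate 1. Endothelial markers had a mean of 0.03 (adjusted p = 0.349), with Cldn5 at 0.62 and Kdr at 0.43. Their mean turned to -0.023 without knockout replicate 1 and was 0.058 and 0.069 without knockout replicates 2 and 3. Macrophage and monocyte markers had a mean of -0.09 (adjusted p = 0.349), and Cd14 with -0.79 and Plac8 passed adjusted over the list alone. Plac8 lay below the background level in knockout hearts and was lower there by at least 0.26, or 0.14 without wild-type replicate 2. Without knockout replicate 1 4 members passed over the list alone. The list passed downward without wild-type replicate 1 (adjusted p = 0.0158) or knockout replicate 1 (mean -0.29, adjusted p = 4.04e-05), and its mean was 0.013 and 0.044 without wild-type replicate 3 and knockout replicate 2. For the channel genes, and for markers of smooth muscle, atrial and ventricular cardiomyocytes, fibroblasts, epicardium, platelets and T cells, the mean, the median and the test differed in sign.

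On the first principal component, with 40.4% of the variance, wild-type replicates 1 and 2 lay at -24.0 and -26.9 and the knockout hearts at 13.2 to 15.6. Wild-type replicate 3 lay at 6.77, between them. On the second component, with 21.2% of the variance, knockout replicate 1 lay at -24.7, apart from the other knockout hearts at 14.8 and 9.07 and from the wild-type hearts at -6.91 to 9.13. Wild-type replicate 3 had a mean Pearson correlation of 0.991 with the knockout hearts and 0.987 with the other wild-type hearts. These were taken across probes, which are not independent replicates. The Cenpf value of wild-type replicate 3, 8.04, lay above the highest knockout value of 6.68. No pair of arrays shared more than 0.0309% identical values.

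**Figure D3:**
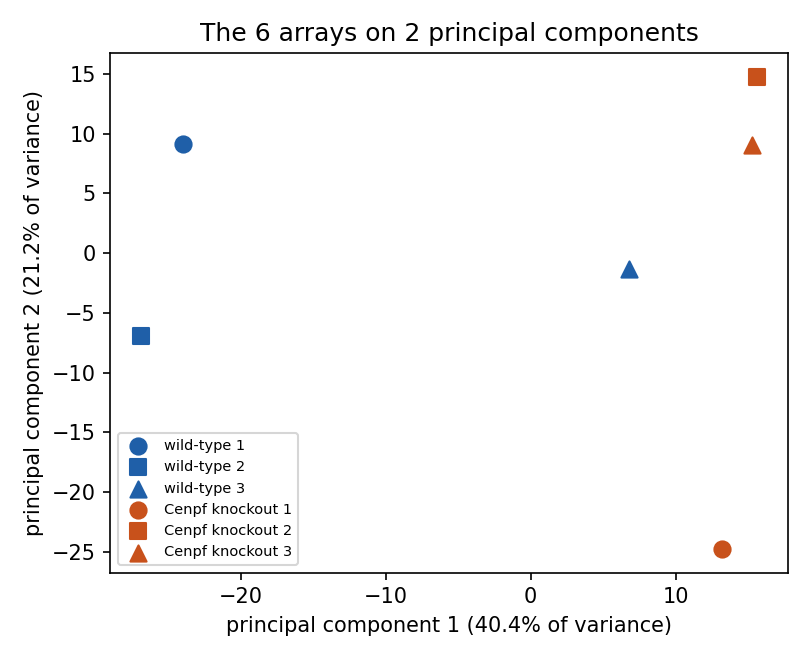
The 6 arrays on the first principal component (horizontal axis, 40.4% of the variance) and the second (vertical axis, 21.2% of the variance); blue marks are wild-type and orange marks Cenpf knockout hearts. Wild-type replicate 3 lies at 6.77 on the first component, nearer the knockout hearts at 13.2 to 15.6 than wild-type replicates 1 and 2 at -24.0 and -26.9.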

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

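The alternatives were fixed before the data were examined, except for 1 filter chosen after seeing the data, and the 13 unshifted lists described were chosen after their results were seen. That filter, at the median of probes with 1 symbol, was first run in place of the planned one at the median of all probes, which replaced it after its values were seen. It gave 2 calls, both among the 6, 103 probes in the second count and 11 lists, and tests fewer probes, Cenpf, Mmp3 and Olfr872 not among them. The 6 calls became 9 with array medians subtracted, 6 with quantile or cyclic loess normalization, 8, of which 5 were among the 6, with either planned filter on dim probes and 9 with the mean of a gene's probes or at an adjusted p under 0.1. They became 1 over all probes of the table, which adds probes to the adjustment and to the pooling of variances alike. There were 22 with a trend and robust variance model, 33 with array weights and 0 with the plain linear model, where 1791 probes had an unadjusted p under 0.05. Leaving out 1 array gave 1 to 293. The 186 probes became 123 above the median of all probes, 437 over all probes, 403 with array weights, 54 with the plain model, 460 at a 1.3-fold and 45 at a 2-fold change, and 121 to 565 with 1 array left out. Cenpf kept its direction throughout, at -2.07 with an adjusted p of 0.281 over all probes and of 0.476 with the plain model, and at -2.27 to -1.92 with 1 array left out. The range of its adjusted p was 0.00508 to 0.476. The 14 lists became 0 with an estimated correlation and 0 by fry, where the smallest adjusted p were 0.126 and 0.0503, and 10 to 16 with 1 array left out. The plain model lacks the pooling of variances, and other settings change the probes or arrays. Which part of a setting moved the results was not tested.

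With the replicate number as a block there were 11 calls, all 6 among them, 260 probes in the second count, 12 lists and Cenpf at -2.07, and the lists of complex I and of complexes III to V did not pass (adjusted p = 0.0748 and adjusted p = 0.0689). Same-numbered hearts did not deviate together (correlations of -0.114, -0.158 and -0.0031), and the labels do not pair the mice.

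Of 1874 alternatives of 106 other named genes, 1792 kept direction and side of the threshold, 61 newly passed, 18 no longer passed and 3 reversed. Myh6 ranged from -0.023 to 0.14 with 1 array left out. Xist reached -0.051 with array weights and ranged from -0.16 to 0.36 with 1 array left out. Of 513 alternatives of 27 lists, 433 kept both, 52 no longer passed, 10 newly passed and 18 reversed by the test's direction. The channel list reversed at means of 0.016, 0.0034 and -0.0016 under the 3 normalizations, 0.023 with the background filter, 0.028 above the median of probes with 1 symbol, and -0.0060 with the trend model and by fry, and ranged from -0.091 to 0.14 with 1 array left out. With array weights the matrix list reversed to -0.050 and the DNA replication list to -0.016. With 1 array left out these ranged from -0.097 to 0.15 and from -0.016 to 0.043, the macrophage list from -0.29 to 0.044 and the vesicle transport list from -0.051 to -0.017. With all arrays kept, the members that passed adjusted over the list alone ranged from 0 to 13 for natriuretic and fetal genes, 0 to 9 for heat shock, 0 to 8 for mitosis, 0 to 6 for atrophy, 0 to 5 for adipocyte and 0 to 4 for lymphatic genes, 2 to 10 for fatty acid, 2 to 8 for interferon, 6 to 13 for immediate early and 4 to 5 for erythrocyte genes, the highest of each with array weights. Signal over background limits the mitosis list and Mmp3 in wild-type hearts, which lie near the background level.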

Other observations

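The tests of other divisions of the arrays and of neighbouring genes in wild-type replicate 3 were set before their results were seen, and all other tests of an explanation after. The bounds of the tests on the neighbours of immediate early genes and on neighbouring genes that differ between the genotypes were both changed once their results were known, which moved the outcome of the first and not that of the second.

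Among lists not described so far, circadian clock genes had a mean difference of -0.09 (adjusted p = 0.201), with Ciart at -0.67 and Arntl, also called Bmal1, at 0.67. Without wild-type replicate 3 that list passed downward (mean -0.17, adjusted p = 0.0120), and without wild-type replicates 1 and 2 its mean was -0.052 and -0.056. Genes of the ATF4 and unfolded protein response had a mean of 0.08 (adjusted p = 0.154), with Atf3 at 0.98 and Ppp1r15a at 0.36, and passed without knockout replicate 2 (adjusted p = 0.0307). Of genes known to differ between laboratory strains, Nnt with -0.84 and Glo1 with 0.50 passed adjusted over the list alone, where 4 did without wild-type replicate 3, and the list had a mean of -0.11 (adjusted p = 0.337). The names of the Nnt and Glo1 probes were not checked by their neighbours in probe order. Genes of vesicle transport had a mean of -0.03 (adjusted p = 0.835), with Rab5a at 0.45 and Vamp3 at -0.43, and ranged from -0.051 without wild-type replicate 3 to -0.017 without wild-type replicate 1.

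With 10 ways to divide 6 arrays into 3 and 3, no share under 0.05 can be reached. The real division gave 6 calls and the highest other 0. It gave 186 probes in the second count, where the highest other gave 150, with knockout replicate 1 beside wild-type replicates 1 and 2. It gave 14 shifted lists, where 5 of the 10 divisions, the real one included, gave at least as many and the highest gave 18. For calls and probes, 1 of the 10 divisions, the real one, gave as many.

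Wild-type replicate 3 lay nearer the knockout hearts than the other wild-type hearts did on the first principal component, at 6.77. Of the 150 genes that deviated most in it from the other wild-type hearts, 146 lay nearer the knockout mean, which that choice itself favours. Of the 150, 61 lay outside the range of the other 5 hearts, among them Cyp2b10 at 9.40 and Cxcl13 at 9.30. Cwc22 read 8.11, 8.92 and 11.32 in wild-type replicates 1, 2 and 3, and 11.01 to 11.38 in the knockout hearts. In the same order Gm14403 read 10.92, 11.07 and 8.60, and 8.66 to 8.70. H2-Ea read 9.23, 9.69 and 6.47, and 5.46 to 5.52. All these genes were singled out after their values were seen. A swap with a knockout heart is argued against by Cenpf, which lay 1.36 above the highest knockout heart, where the larger group SD was 0.36. A lower share of heart muscle cells, with the other cell types unchanged among themselves, would raise the markers of all of these. Fibroblast markers lay lower by -0.22 and platelet markers higher by 0.37, each beyond its spread over genes. That spread was taken in 1 heart, and fibroblast genes vary together (estimated correlation 0.74). A lower share along with other changes in the cell types is therefore not excluded. Ventricular cardiomyocyte markers lay at -0.011 in wild-type replicate 3, against -0.019 and -0.012 in wild-type replicates 1 and 2. A different genetic background may contribute and stays open. The 150 most deviating genes formed 14 neighbouring pairs, where the median of 10000 random sets was 12 and their 95th percentile 18 (permutation p = 0.313). Another array reached 16. That count does not weigh how far a single gene such as Cwc22, Gm14403 or H2-Ea lay from the other wild-type hearts.

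Immediate early genes were higher in the knockout hearts, by 0.24 between the lowest knockout and the highest wild-type list mean. Handling at dissection could raise them too, and no record separates handling from genotype, so handling and genotype cannot be told apart. A genetic background difference next to these genes was not decided either, since 20.8% of the 24 had a differing neighbour, where the median of random sets was 33.3% and their 5th to 95th percentiles 16.7% to 50%. The share lay below that median, which the bound first set would have counted against this explanation, but not beyond the spread. A response to the loss of Cenpf stays open and was not tested.

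Genes that differ between strains may be among those that differ between the genotypes. The 472 genes at an unadjusted p under 0.01 formed 132 neighbouring pairs, where the median of random sets was 102 and their 95th percentile 119 (permutation p = 0.0042). Those random sets were drawn from all genes, also those below the background level. The sets for wild-type replicate 3 and for the immediate early genes were drawn from genes above it. Of the 472, those above that level formed 83 pairs, for which no random sets were drawn, so an excess there was not tested. For as many genes, the division with knockout replicate 1 beside wild-type replicates 1 and 2 gave 129 pairs, close to the 132 of the real one. Neighbours can also share regulation. Chromosome 17, which carries H2-Ea, held 40 of the genes where 22.3 are expected (one-sided Fisher's exact test, adjusted p = 0.00545 over the chromosomes). That test takes genes as independent, which neighbours need not be, so its p can be too small. It was not run on the other divisions of the arrays. Around Cenpf itself, 5% of 40 flanking genes differed, Atf3 and Mark1, where the median run of neighbours had 2.5% and 24.5% of runs had as many, which decides nothing on a segment carried along with the targeted allele.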
